A study of Arabidopsis thaliana with 4 samples.

How the data were processed

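Gene expression was measured in the above-ground tissue of Arabidopsis thaliana plants grown on soil for 14 days, from wild-type plants and from plants carrying the php mutation. Each genotype had 2 arrays, called replicates I and II, and per the labels each replicate was made of 3 independently derived samples. Per the labels' protocols, total RNA was isolated on silica columns and biotin-labelled for Affymetrix ATH1 arrays, which measure each transcript with a set of short oligonucleotide probes called a probe set. The deposited values are on a log2 scale, and per the series' design text the authors corrected the background and normalized the arrays together with GCRMA, a method that models background from probe sequence and leaves unexpressed probe sets at a low floor. MAS5 also appears in the submitters' processing notes with no stated role, and software versions are not given in the sources used here. A log2 difference of 1 is a 2-fold difference. Arrays have no read depth, so the number of arrays limits the precision.

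The table held 22810 probe sets. The 64 Affymetrix control probe sets were left out of the comparison, as were the 6824 probe sets in the lowest 30% by mean level over the 4 arrays, with a mean log2 level up to 2.64. That left 15922 probe sets. The 4 arrays had medians of 5.64, 5.64, 5.59 and 5.61 for wild-type I, wild-type II, php I and php II, so no further normalization was applied. Gene names came from the platform annotation, which listed 14016 probe sets, 13513 of them with 1 gene and 503 with several. The other 8794 probe sets, 8730 of them not controls, are unnamed here, and no gene was named from a probe set with several. Through gene identifiers, 13436 probe sets were matched to a locus of the RefSeq annotation of assembly TAIR10.1, and 8749 such genes were tested. That annotation was used for names and for the order of genes along chromosomes, and no coordinates are given because no assembly is stated for the array annotation.

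Differences between php and wild-type were tested per probe set with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend of the variance on the level, two-sided, with Benjamini-Hochberg adjustment over the 15922 probe sets. A probe set was called at an adjusted p under 0.05. Intervals are 95% confidence intervals from the same fit, and ± values are SD over 2 arrays. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so every p-value rests on the model, which shares information on the spread across probe sets. The model had 2 residual and 1.98 prior degrees of freedom. On simulated data for this comparison, over 15922 probe sets, the fit called 52.2% of the 67 changed 2-fold, 92.5% of the 67 changed 4-fold and 93.9% of the 66 changed 8-fold, with 4 false calls. With no change simulated it called 0 probe sets, with 5.11% at an unadjusted p under 0.05. The simulation drew each probe set independently with the spread that the fit itself assumes, and without effects shared across an array. It therefore checks the procedure and does not show that the p-values hold on these arrays.

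Before the data were examined, 22 gene lists were fixed by locus and 5 by name pattern, covering flowering, chromatin, hormones, stress, metabolism, cell division and other tissues. The lists by locus held 315 distinct loci, of which 39 were measured by a probe set named here and 28 were tested. Lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, taking the brightest probe set of a gene and adjusting over the 9 lists tested. The rule for the genes named in the text was also fixed beforehand. It took all measured members of the PAF1 complex and the FLC clade with FT and SOC1, then the 12 largest rises and the 12 largest falls among called probe sets with 1 gene and no overlap between genotypes. Where none was called in a direction, it took the 5 with the smallest p, and per list up to 4 called members or else the 2 with the largest difference. Further list members were named beyond this rule. Other genes named outside it were chosen after their values were seen, as stated where they appear. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

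Alternatives fixed beforehand were other filters on dim probe sets, other variance models, quantile normalization, median centring, a replicate block, a minimum fold of 1.2, a rule of unadjusted p with 2-fold, leaving out each array, and for the lists an estimated correlation and the mean of a gene's probe sets. An adjusted p under 0.1 and leaving out the lowest 40% were added after the data were seen.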

Results

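Transcript levels were compared between wild-type Arabidopsis plants and php mutants, in aerial tissue at 14 days of age. PHP, PLANT HOMOLOGOUS TO PARAFIBROMIN, is a subunit of the PAF1 complex, which travels with RNA polymerase II during transcription elongation. Each genotype had 2 arrays, and each array held RNA from 3 independently derived samples. Over the 15922 probe sets tested, the 2 wild-type arrays correlated at r = 0.994 and the 2 php arrays at r = 0.993, across probe sets, which are not independent replicates. Between genotypes r was 0.991 and 0.992 for arrays with the same replicate number, and 0.988 for both pairs with unlike numbers. A difference of at least 2-fold separated 1.16% of probe sets between the wild-type arrays and 1.16% between the php arrays. Between genotypes it separated 1.60% and 1.59% for the same number, and 2.18% and 2.62% for unlike numbers.

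The comparison of php with wild-type asks which transcripts depend on PHP in shoots. AT4G12490 and AT4G12500, a pair of genes of the lipid-transfer protein family, fell in php. AT4G12490 was at 9.55 ± 0.01 in wild-type and 6.66 ± 0.15 in php (log2, SD, n = 2 arrays each), a 7.42-fold lower level. Its log2 difference was -2.89 with a standard error of 0.10 and a 95% confidence interval of -3.16 to -2.63 (limma adjusted p = 0.043). AT4G12500 was at 5.90 ± 0.08 in wild-type and 3.56 ± 0.07 in php, 5.06-fold lower, with a log2 difference of -2.34 (SE 0.09, limma adjusted p = 0.045). These genes stand next to each other in the TAIR10.1 gene order apart from 1 gene model, AT4G12495, and they share a family with their neighbours AZI1 and EARLI1, so shared hybridisation between them is not excluded.

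Of the 15922 probe sets tested, 5 were called, 1 higher and 4 lower in php, and all 5 differed by at least 2-fold. The other 3 called probe sets are unnamed here. One rose from 2.82 ± 0.15 in wild-type, near the background floor, to 5.90 ± 0.01 in php (limma adjusted p = 0.043), so the size of its rise is not measured well. The other unnamed probe sets fell, the first from 5.57 ± 0.01 to 3.37 ± 0.00 and the second from 8.60 ± 0.03 to 6.56 ± 0.05, 4.57-fold and 4.11-fold lower (limma adjusted p = 0.043 each). Unadjusted p was under 0.05 for 3856 probe sets, 24.2% of those tested, where chance gives 796.1, with 1799 higher and 2057 lower in php. Genotypes did not overlap on 9638 probe sets, or 60.5%, where chance gives 33.3% for 2 arrays against 2. Both chance values take probe sets as independent, but all share the same 4 arrays, so a shift of a whole array moves many together. In the tenth of probe sets just above the filter, 65.6% were higher on both php arrays and 7.4% lower on both. These counts are therefore no measure of how many transcripts depend on PHP. With any 1 of the 4 arrays left out, limma called 0 probe sets, with 1912 to 4006 at an unadjusted p under 0.05. Without the filter on dim probe sets the count was also 0 (8020 unadjusted), and with the lowest 50% left out it was 21, including the 2 of these 5 that were still tested. With the replicate number as a block in the fit, it was 0 (4311 unadjusted).

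No probe set with a gene name was called higher in php. The 5 with the smallest p in that direction did not pass. AT5G62360, of the invertase and pectin methylesterase inhibitor family, was at 10.87 ± 0.05 in wild-type and 11.98 ± 0.03 in php, a log2 difference of 1.11 (SE 0.05, limma adjusted p = 0.051). AT3G28500, an acidic ribosomal protein gene, differed by 1.77 and AT3G26460 by 1.49 on the log2 scale. AT1G20390, a pseudogene in the TAIR10.1 annotation, was at 2.97 in wild-type, near the floor, and 5.62 in php, and AT1G70270 differed by 1.31, and limma gave these 4 an adjusted p of 0.083 each. AT5G62360 passed when the lowest 40% or 50% of probe sets were left out (limma adjusted p = 0.031 and 0.021), within a range of 0.021 to 0.407 over its alternatives.

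**Figure D1:**
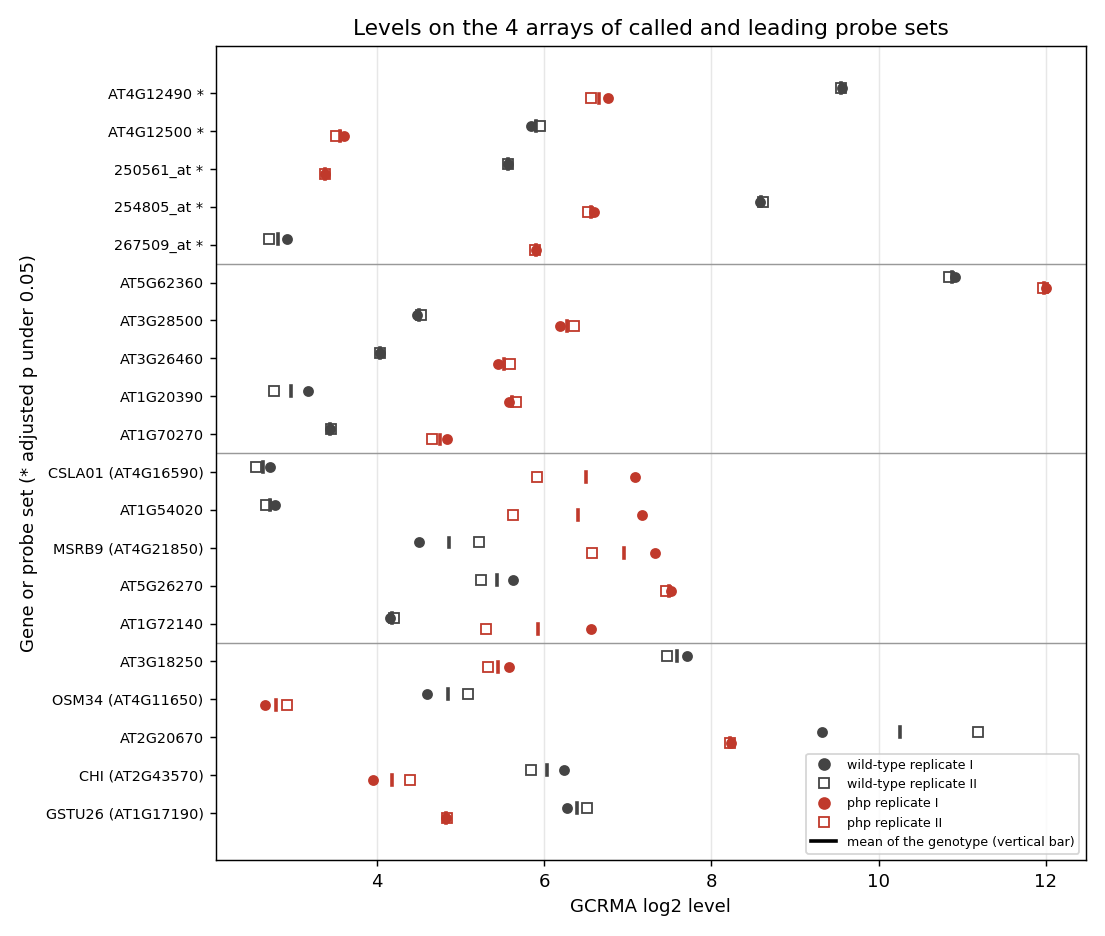
GCRMA log2 level (horizontal axis) of 20 genes or probe sets on each of the 4 arrays, with wild-type in grey, php in red, replicate I as filled circles, replicate II as open squares and the mean of each genotype as a vertical bar. The blocks from top to bottom are the 5 called probe sets, the 5 named genes higher in php with the smallest p, and 5 further genes higher and 5 lower in php from those at least 2-fold apart, and AT4G12490 lies at 9.56 and 9.55 in wild-type and at 6.77 and 6.56 in php.

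At an unadjusted p under 0.05 and at least 2-fold, 122 probe sets differed, 63 higher and 59 lower in php, and 58 of them have a locus here, 30 higher and 28 lower. Those not called had limma adjusted p between 0.051 and 0.203, and the genes named in this and the next paragraph were chosen after their values were seen. CSLA01, of the cellulose synthase-like A family, was at 2.63 ± 0.12 in wild-type and 6.50 ± 0.83 in php (limma adjusted p = 0.093). AT1G54020, a GDSL-type lipase gene, was at 2.72 ± 0.07 and 6.40 ± 1.08 (limma adjusted p = 0.096). Both lay at the background floor in wild-type, where probe sets with no plant target were at 2.29 to 2.54, so no fold is given for them. MSRB9, a methionine sulfoxide reductase gene, was 4.25-fold higher and AT5G26270 4.13-fold higher in php. The bifunctional lysine degradation gene AT4G33150, LKR/SDH, differed by 1.11 (SE 0.09, limma adjusted p = 0.084), and the jacalin-related lectin genes JAL23 and JAL22 by 1.11 and 1.01, with JAL23 at 0.70 without php replicate I.

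Among genes lower in php, OSM34, which encodes an osmotin, was at 4.84 ± 0.34 in wild-type and 2.79 ± 0.19 in php, near the floor (limma adjusted p = 0.088). The chitinase gene CHI differed by -1.86 (limma adjusted p = 0.093) and AT2G43590 by -1.04. GSTU26, a glutathione S-transferase of the tau class, was at 6.39 ± 0.17 and 4.83 ± 0.01, a difference of -1.56, and the alkenal reductase gene AER at 7.51 ± 0.03 and 6.07 ± 0.10, a difference of -1.44. The legume lectin family gene AT5G03350 was abundant in both genotypes, at 12.10 ± 0.03 and 10.77 ± 0.07, a difference of -1.33 (SE 0.06, limma adjusted p = 0.051). AT3G18250 differed by -2.14 (SE 0.15). The 2 wild-type arrays disagreed on AT2G20670, at 9.32 and 11.19 against 8.23 and 8.22 in php, and without wild-type replicate II its difference was -1.09 in place of -2.03.

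**Figure D2:**
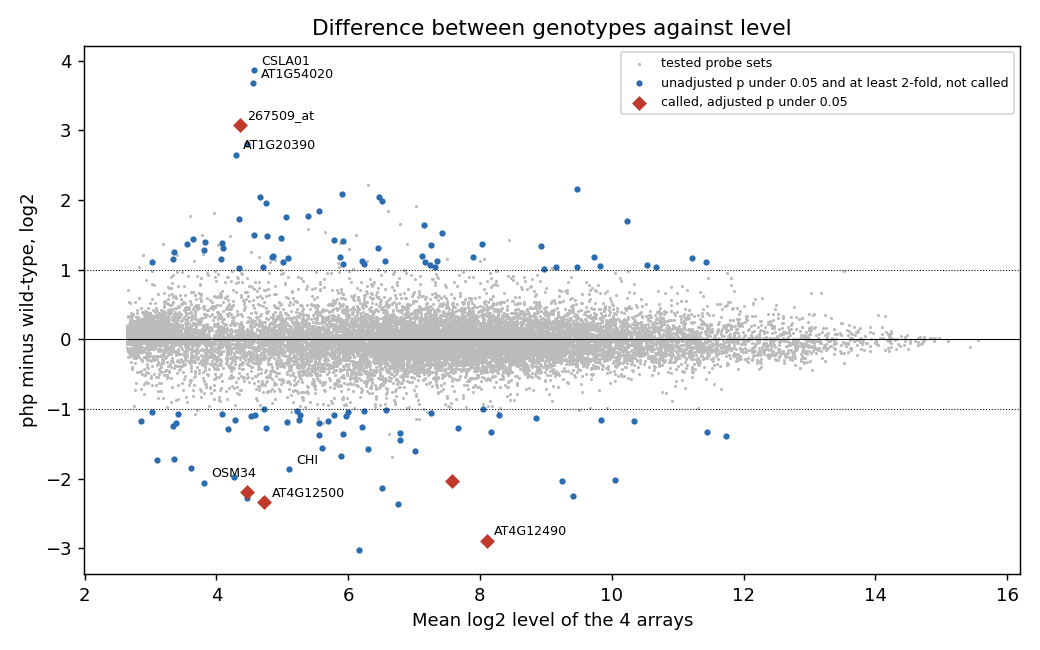
The log2 difference of php minus wild-type (vertical axis) against the mean log2 level of the 4 arrays (horizontal axis) for the 15922 probe sets tested, with dotted lines at 2-fold. Red diamonds are the 5 called probe sets and blue points the others of the 122 at an unadjusted p under 0.05 and at least 2-fold, with AT4G12490 at -2.89.

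Of the gene lists fixed before the data were examined, 9 had at least 3 tested members, and limma's camera called 0 of them, with 3 at an unadjusted p under 0.05. With an estimated correlation it also called 0, with 0 at an unadjusted p under 0.05. Over all probe sets tested, 0 list members passed, and 7 passed when adjusted over the list alone. Among the 7, GI and PYK10 were the only tested members of their lists, so their p was in effect unadjusted. The lists are short, and 24.2% of all probe sets tested had an unadjusted p under 0.05. Passing over the list alone therefore does not set a member apart from other genes.

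All 3 tested members of the auxin response list were higher in php on both arrays than on either wild-type array, with a median log2 difference of 1.30, or 0.68 without wild-type replicate II. WES1, also called GH3.5, which conjugates amino acids to auxin, was at 5.21 ± 0.00 in wild-type and 6.63 ± 0.51 in php, a log2 difference of 1.42 (SE 0.27, limma adjusted p = 0.113). It was the 1 member that passed when adjusted over the list alone (limma adjusted p = 0.019). IAA29 differed by 1.30 (SE 0.65) and GH3.3 by 0.96 (SE 0.37), and neither passed. IAA29 ranged from 0.48 without wild-type replicate II to 2.11 without wild-type replicate I, and GH3.3 was at 0.53 without php replicate I. Camera gave the list an adjusted p of 0.102, and 0.764 with an estimated correlation, in limma. Without wild-type replicate I the list passed (adjusted p = 0.040, range over 12 alternatives 0.040 to 0.764).

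The 3 tested cell cycle genes had lower means in php, with a median log2 difference of -0.43. The Aurora kinase genes AUR2 and AUR1, which act in mitosis, differed by -0.47 (SE 0.12) and -0.43 (SE 0.10), and both passed when adjusted over the list alone (limma adjusted p = 0.025 each) but not over all probe sets. PRL, which encodes a subunit of the replicative helicase, differed by -0.20 and did not pass, and it was at 0.01 without php replicate II. The list had a camera adjusted p of 0.102, and 0.764 with an estimated correlation, in limma. It passed without php replicate I (adjusted p = 0.019) and without the filter on dim probe sets (0.040), within 0.019 to 0.764 over 12 alternatives.

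The 4 tested genes of flavonoid and anthocyanin synthesis had lower means in php, with a median log2 difference of -0.46, and 0 passed in either adjustment. That median was -0.20 without wild-type replicate II and -0.73 without wild-type replicate I, and the glucosyltransferase gene AT4G14090 overlapped between genotypes (-0.28, or -0.01 without wild-type replicate II). The anthocyanin malonyltransferase gene AT5MAT was at 3.61 ± 0.47 in wild-type and 2.77 ± 0.25 in php, near the floor, so the size of its difference is not measured well. DFR, which encodes dihydroflavonol reductase, was at 8.40 ± 0.49 and 7.84 ± 0.06, a difference of -0.56, or -0.21 without wild-type replicate II. In limma, the list had a camera adjusted p of 0.102, and 0.764 with an estimated correlation. It passed without wild-type replicate I (adjusted p = 0.0011) and without the filter on dim probe sets (0.040), within 0.0011 to 0.764 over 12 alternatives.

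The 4 tested genes of the cold and abscisic acid list had a median log2 difference of 0.25, between 0.05 without php replicate II and 0.64 without php replicate I. The dehydrin gene COR47 was at 10.52 ± 0.22 in wild-type and 11.27 ± 0.11 in php, a difference of 0.75 (SE 0.13), and it passed when adjusted over the list alone (limma adjusted p = 0.019) but not over all probe sets (0.106). COR15A differed by 0.26, COR15B by 0.23 and LTI30 by 0.24, and without php replicate II these were 0.08, 0.01 and -0.45. The list had a camera adjusted p of 0.162, and 0.764 with an estimated correlation, in limma, and it passed without php replicate I (adjusted p = 0.019, range over 12 alternatives 0.019 to 0.797).

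The tested nuclear genes of the light-harvesting and photosystem lists were at 13.49 or above in both genotypes, apart from LHCB4.3 at 9.33, and differed little. Plastid-encoded photosynthesis genes are not in these lists, and their levels and differences ranged more widely. The 3 light-harvesting genes ranged from -0.09 for LHCB4.2 to 0.07 for LHCB4.1, with a median of 0.00 and a mean of -0.01, which differ in sign, and camera's direction was down. The 4 photosystem subunit genes ranged from -0.06 for PSBW to 0.05 for PSBY, and PSBY was at -0.01 without php replicate I. The jasmonate list had a median of -0.11 but a mean of 0.23, and no direction is settled for it. Its median was 0.74 without wild-type replicate I and -0.62 without wild-type replicate II, and camera's direction was up in the first and down in the second. The defensin genes PDF1.2 and PDF1.2b overlapped between genotypes, at -0.15 and -0.07, and at 0.58 and 0.90 without wild-type replicate I. The thionin gene THI2.1 differed by 1.48 (SE 0.73), or 0.52 without php replicate I. JMT, the jasmonate methyltransferase gene, differed by -0.32, or -0.04 without php replicate II, and 0 of these 11 genes passed. In limma these 3 lists had camera adjusted p of 0.999 each, and 0.999 each with an estimated correlation.

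Of the WRKY transcription factor genes, 6 were tested and 0 passed, with WRKY20 at 0.34 and WRKY53 at -0.26, or 0.90 without php replicate I (camera adjusted p 0.656, and 0.764 with an estimated correlation, in limma).

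Smaller lists had 1 or 2 tested members and no test of the list. GI, the clock and photoperiod gene GIGANTEA, was at 9.50 ± 0.06 in wild-type and 9.93 ± 0.12 in php, a log2 difference of 0.43 (SE 0.08). As GI was the 1 tested clock gene, its p over the list alone had nothing to be adjusted for (limma unadjusted p = 0.0059). Over all probe sets it did not pass (limma adjusted p = 0.112). Of the glucosinolate genes, UGT74B1 differed by 0.22 (SE 0.05, limma adjusted p = 0.021 adjusted over the list alone, 0.125 over all probe sets) and BCAT4 by 0.03. The autonomous pathway genes LD and FY, which act upstream of FLC, differed by -0.37 (SE 0.22) and 0.16 (SE 0.09), and LD was at -0.09 without php replicate II and FY at 0.11 without wild-type replicate I. SAG101 of the salicylate and defence list differed by 0.29, or 0.19 without wild-type replicate I, and WRKY53 of the senescence list by -0.26, and neither passed. STZ, an early touch and wound gene, varied more within genotypes, at 7.49 ± 2.59 and 8.64 ± 2.12, and its difference of 1.15 was -0.68 without wild-type replicate I. The measured heat shock genes and the iron regulator gene BHLH101 were below the filter in both genotypes, between 2.18 and 2.59.

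**Figure D3:**
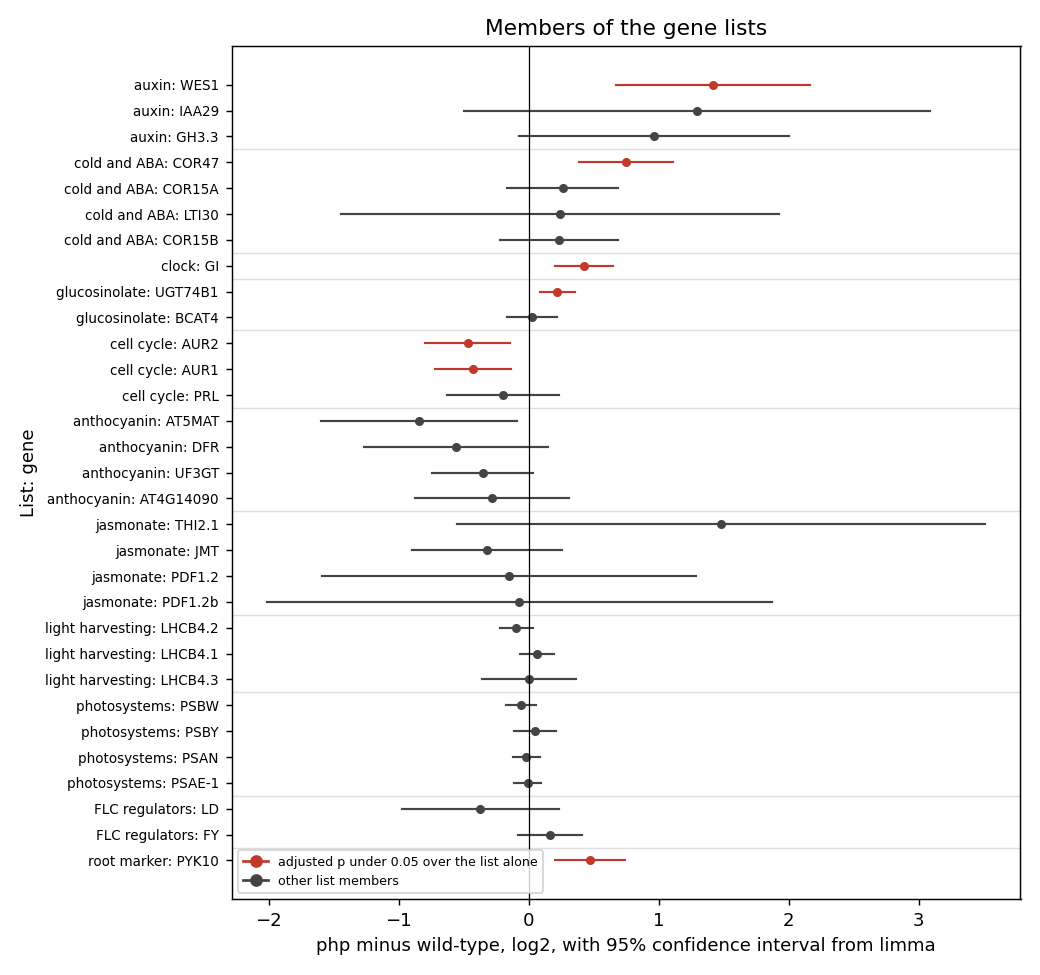
The log2 difference of php minus wild-type (horizontal axis) for tested members of 11 of the gene lists, each a point with its 95% confidence interval from limma. Red marks the 7 genes with an adjusted p under 0.05 over the list alone, from 1.42 for WES1 to -0.47 for AUR2. For GI and PYK10, each the only tested member of its list, this p is in effect unadjusted.

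Markers of other organs were compared to show whether the harvests differed in tissue. The root marker PYK10, a beta-glucosidase gene of endoplasmic reticulum bodies that seedling shoots also express, was at 11.77 ± 0.15 in wild-type and 12.24 ± 0.10 in php. Its log2 difference was 0.47 (SE 0.10). As the 1 tested root marker, its p over the list alone had nothing to be adjusted for (limma unadjusted p = 0.0080). Over all probe sets it did not pass (limma adjusted p = 0.115). The root hair gene EXPA7 was at the floor, at 1.91 ± 0.00 and 1.93 ± 0.00. The 4 measured flower markers had means below the filter in both genotypes. AMS, a tapetum gene, was at 2.14 ± 0.01 in wild-type and 2.18 ± 0.01 in php, and SPL and INO at 2.24 and 1.98 in wild-type and 2.28 and 2.01 in php. AT5G07230 had the largest difference of the 4, at 2.33 ± 0.01 and 2.52 ± 0.22, with php replicate I at 2.67, just above the filter's 2.64.

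The PHP transcript was not analysed here, so the genotype labels have no check from the mutated gene. Transcripts of the other PAF1 complex subunits, the FLC clade, FT, SOC1, PRC2 and LHP1, known PRC2 targets, seed maturation, phosphate starvation and cytosolic ribosomal proteins were not analysed here either, apart from AT3G28500.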

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

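The test of RNA integrity was chosen only after the differences of the control probe sets were seen. Control probe sets, which the comparison of genotypes did not use, carried a signal that differed between them. The 25S rRNA control probe set was at 5.40 and 5.50 on the wild-type arrays and 6.30 and 6.97 on the php arrays, a log2 difference of 1.18, and the 5S rRNA control at 4.38 and 4.09 against 5.05 and 5.59, a difference of 1.09. Of the plant probe sets within 0.5 log2 units of their level, 99.3% and 98.1% had a smaller difference. The 18 probe sets of the bacterial spike-in transcripts bioB, bioC, bioD and cre, added at hybridization, were all higher on both php arrays, by a median of 0.35 (0.22 to 0.51). The 24 probe sets of the poly(A) spike-ins dap, lys, phe and thr had a median difference of -0.08 (-0.31 to 0.03).

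The rRNA controls were set beside the plastid-encoded genes, whose transcripts also lack stable poly(A) tails and whose 69 probe sets had a median difference of 0.08, above the random lists of the same size and level (-0.06 to 0.01 for their middle 95%). The pattern was not the same on each array, since their median deviation was 0.05 on wild-type I, -0.11 on wild-type II, -0.05 on php I and 0.16 on php II, and camera gave p = 0.696 in limma with an estimated correlation of 0.68. Whether RNA integrity differed between the genotypes cannot be decided from the 3' minus 5' log2 difference. It changed by -0.16 for GAPDH (pooled SD 0.06), 0.07 for actin (0.05) and 0.01 for ubiquitin (0.08). At this number of arrays the pooled SD is also the standard error of the change. The changes are too close to that error to be read, so a difference in RNA integrity stays open. More RNA without poly(A) tails in the labelled pool is neither supported nor excluded, and an effect of php on rRNA itself, which was not tested, also stays open. For the first, the 10 mitochondrially encoded probe sets tested had a median difference of 0.046, at the 37.7th percentile of random lists, on the side set beforehand as speaking against it, but below their middle of 0.06 by far less than their spread (-0.08 to 0.19), with members in both directions and most near the floor.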

How the results depend on the processing

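An adjusted p under 0.1 and leaving out the lowest 40% of probe sets were chosen after seeing the data. The 5 probe sets called with limma, 1 higher and 4 lower in php, were 5 (1 and 4) without a variance trend and after median centring, 4 (1 and 3) with a robust fit and 6 (1 and 5) after quantile normalization. Those fits shared 5, 5, 4 and 5 of the original calls. With a minimum fold of 1.2 there were 3 (1 and 2). Without the filter on dim probe sets limma called 0 (0 and 0), with 8020 at an unadjusted p under 0.05, 74.4% of them higher in php. With the lowest 50% left out it called 21 (8 and 13), and this filter removed 3 of the 5 original calls untested while the 2 still tested passed (limma adjusted p = 0.019 each). With the lowest 40% left out it called 8 (2 and 6). An adjusted p under 0.1 gave 516 (227 and 289), and an unadjusted p under 0.05 with at least 2-fold 122 (63 and 59). Without each array in turn, which leaves 1 array assumed to vary like the other genotype's 2, counts ranged from 0 to 0 in both directions. With a replicate block there were 0 (0 and 0), with 4311 at an unadjusted p under 0.05 and 1 residual degree of freedom. The labels say of the numbers I and II only that they name replicates. The replicate I minus II deviations correlated at 0.518 between genotypes, across probe sets, and arrays with the same number were the more alike across genotypes. The main fit leaves out such a shared replicate effect. With 2 pairs, whether the numbers mark pairs cannot be settled here, and the 5 calls hold only without the block. The block changed no call of a gene list. The differences of the 5 called probe sets kept their direction in all 30 values from normalization and leaving out an array, the settings that can move a difference. Their size was up to 3.19 log2 units and never under 2. The genotypes did not overlap on any of these 5. Leaving out an array therefore could not reverse a direction, and the kept direction is no evidence of robustness there. Of 62 values under all settings 29 passed, with limma adjusted p from 0.019 to 0.407. Gene lists called numbered 0 except for 3 without the filter on dim probe sets and 0 to 2 without each array, and the cause was not tested. Over 110 named genes and their other settings, 1297 of 1369 values kept direction and side of the threshold, 29 uncalled values changed sign, 10 moved past the threshold and 33 no longer passed. All 33 belong to the 5 called probe sets. All of the other genes were uncalled in the main fit, and many settings cannot move a difference, so the 1297 do not measure robustness.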

Other observations

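The test of the background floor was chosen only after the shift of the dimmest probe sets was seen, and the genes named here were chosen after their values were seen.

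Of the 8749 genes tested, 4 were at a mean under 3 log2 units in 1 genotype and at least 4-fold apart. CSLA01, AT1G54020 and the pseudogene AT1G20390 were near the floor in wild-type, at 2.63, 2.72 and 2.97, and at 6.50, 6.40 and 5.62 in php. OSM34 was at 4.84 in wild-type and 2.79 in php. None of the 4 passed (limma adjusted p from 0.083 to 0.096). Of the 69 plastid-encoded probe sets tested, limma called 0, with 7 at an unadjusted p under 0.05, all 7 higher in php. That is a smaller share than the 24.2% of all probe sets tested. The widest difference among them belonged to petD, which encodes a cytochrome b6f subunit, at 5.98 in wild-type and 6.81 in php (SE 0.34), and the lowest to rpoA, a subunit of the plastid RNA polymerase, at -0.32 (SE 0.12). The mitochondrial gene ccb382 was at 6.44 and 5.70 (SE 0.18, limma adjusted p = 0.139).

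Differences between the genotypes were weakly shared by adjacent genes. Both members of 11 pairs of adjacent protein-coding genes in the TAIR10.1 order differed by at least 0.6 log2 units, in the same direction for 9 of them. OSM34, near the floor in php, and its neighbour SR, with a difference of -0.74, were both lower in php. AFR differed by -0.87 and AT2G24550 by -1.04, and XTH18 by 0.97 and XTH19 by 0.77. None of these 6 genes passed (limma adjusted p from 0.088 to 0.368). XTH18 and XTH19 share a family name, so shared hybridisation between them is not excluded. The 11 pairs were picked by size, and the share in the same direction by chance was not worked out. They are also not independent, since AT4G27654 is paired with both AT4G27652 and AT4G27657.

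Over 2905 pairs of adjacent genes the php minus wild-type differences correlated at r = 0.087 (Spearman rho = 0.055), across genes, which are not independent replicates, and at r = 0.060 without the genes at least 2-fold apart. A one-sided permutation test with 10000 shuffled gene orders gave 1e-04 for r, the smallest they can give (1.67e-04 after Benjamini-Hochberg adjustment over 5 such relations). A separate one-sided permutation test with fewer shuffles gave 0.0020 for rho. Marked shared probes and a linked block around PHP are both argued against as the whole source, since r was 0.087 without the 91 genes whose probe set suffix marks shared probes and 0.088 without the genes within 150 loci of PHP, against an upper bound of 0.036 from the shuffled orders in each case. Variation between arrays whatever the genotype is a candidate explanation, because the replicate II minus replicate I differences, averaged over genotypes, correlated between adjacent genes at r = 0.094, no less than the genotype differences. An effect of PHP on neighbouring genes is not needed for a correlation of this size, and it stays open.

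The dimmest probe sets were nearly all slightly higher on the php arrays. In the lowest 30% by level, 95.5% of 6823 probe sets were higher in php, by a median of 0.04 log2 units, against 47.1% of the 13648 brightest. In the tenth of probe sets just above the filter, which the comparison kept, 75.4% were higher in php, by a median of 0.09. A background floor that differs between arrays is a candidate explanation, since the 3 TrpnX control probe sets, which have no target in plant RNA, were higher on both php arrays, by a median of 0.081. An effect of the genotype on weakly expressed genes was not tested apart from this. The filter therefore left part of the shift in the comparison.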
